A study of Homo sapiens with 6 samples.

How the data were processed

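RNA sequencing of poly(I:C)-treated primary human epidermal keratinocytes was compared between 3 libraries labelled CTLi and 3 labelled ARID1Ai, taken from the sample titles. Per the labels' protocols, cells were grown in EPILIFE medium, total RNA was taken with a PureLink kit and libraries were made with a TruSeq RNA kit. The submitters' processing notes name TopHat2 2.1.0, Partek 9.0.20.0202 and the build hg19, without saying what each was used for. The deposited table is a signal unit of normalized gene counts, per the file headers and the values, not raw counts: the values are partly fractional and had been scaled by library. The normalization method, the counting rule for shared reads and the use of strand are not given in the sources used here. The table pairs Ensembl gene IDs with names and positions, and 754 of its 14350 entries have no gene name. Of the IDs, 14250 were found in GENCODE release 29, and the positions of 14236 of these (99.9%) overlapped the GRCh38 position. The coordinates are therefore given as GRCh38, although the notes name hg19. The table holds 12380 protein-coding and 864 long noncoding genes. Few genes have low values, so genes with low counts appear to have been removed before deposit. The first percentile of the mean value over the 6 libraries was 23.8 on the deposited scale. Another 3 columns of values could not be tied to a labelled sample and were not analysed here. The columns used for ARID1Ai carry an extra letter after the gene name that the titles do not have.

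Low values piled up on multiples of a step that differed between libraries (0.653 to 1.20 on the deposited scale for 1 read). The depth of each library was estimated from this step. Only 60.9% to 65.7% of the values under 200 reads lay within 0.05 of a whole read, so whole reads were not recovered and the tests for counts planned for that case were not run. The implied depths were 21300000 to 36600000 reads in CTLi and 19200000 to 21500000 in ARID1Ai. CTLi replicates 1 and 2 were thus deeper than the rest, so their low values carry less counting error. Pairs of libraries within a group differed by more than counting noise (chi-square per degree of freedom 2.49 to 6.27), so none was treated as a library deposited again. Separate preparations from one culture would also differ by more than counting noise.

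All values were divided by 1 common factor, 23.52, so that the mean library total was 1000000, which keeps the authors' scaling between libraries. A normalized unit, as used from here on, is therefore 23.52 on the deposited scale, and not 1 read. Genes with a mean of at least 1 normalized unit were tested on log2(value + 1) with limma 3.58.1 in R 4.3.3 (statmod 1.5.0), with trend and without a block, two-sided, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. The siRNA target was also tested with an exact permutation test. Lists of genes, 26 in all, were fixed before the data were examined. Lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, with a correlation estimated from the libraries and with fry. Adjustment was over 20 lists of response, differentiation and cell state, and separately over the lists of other cell types and of RNA quality (mitochondrial and ribosomal). Adjusted p-values in the text are from limma for genes and from camera for lists.

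Genes named in the text were chosen by a rule set in advance: ARID1A; the 10 with the greatest rise and the 10 with the greatest fall among genes past the threshold, with a mean of at least 5 units and no overlap between the 3 values of each group; and for each list up to 4 members past the threshold with the smallest adjusted p and up to 2 members that did not pass, by mean level. A few genes that the rule takes, or that a count would name, are not reported here. Any other named gene is said to have been chosen after its values were seen.

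The tests were tried on simulated values for this comparison with 13944 genes, of which 200 were changed. A log2 change of 1 was recovered for 98.0% of changed genes and a change of 0.25 for 36.0%, while 9.46% of calls were unchanged genes. With no changed gene, 0 were called. One shifted list of 20 was called and 0 of the unshifted ones. Genes were simulated as independent and the lists drawn at random, so this does not test lists whose members vary together.

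Alternatives were another pseudocount, another filter, 2 other scalings, limma without trend and with robust estimation, the replicate number as a block, each library left out in turn, stricter thresholds and other list tests. Transcript lengths and GC content for the closing checks were those of the longest transcript of each gene in GENCODE release 29, which need not be the expressed one.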

Results

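Gene expression was measured by RNA sequencing in primary human epidermal keratinocytes, the main cell type of the outer skin layer, after 24 hours of poly(I:C), a synthetic double-stranded RNA that stands in for viral RNA. The 6 libraries form 2 groups of 3. One group is labelled CTLi and was taken as the control arm, and the other is labelled ARID1Ai, the arm in which ARID1A was knocked down with siRNA. The titles give these groups, while the treatment field of the labels names ARID1A siRNA for all 6 libraries, CTLi included, so what the CTLi arm received rests on its title. All 6 libraries had received poly(I:C), so each value below is a level under stimulation. Nothing in the labels says that the 3 libraries of a group came from separate cultures or donors, so the p-values measure only the spread between these libraries, which may be technical.

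The deposited table holds 14350 genes. Its normalized values summed to 23871155 to 24435082 in the CTLi libraries and to 22667235 to 22991695 in the ARID1Ai libraries. The step between low values, which is what 1 read was worth, implied depths of 34400000, 36600000 and 21300000 reads for CTLi replicates 1, 2 and 3, and of 19200000, 21500000 and 20500000 for ARID1Ai replicates 1, 2 and 3. Values are given below in normalized units, on a scale where the mean library total is 1000000, as mean ± SD with n = 3 libraries per group. Log2 changes are ARID1Ai minus CTLi with a pseudocount of 1, which understates the change of weakly expressed genes. Across genes, log2 values correlated at 0.9964 to 0.9972 within groups and at 0.917 to 0.920 between groups. The median coefficient of variation between libraries was 4.24% in CTLi and 3.97% in ARID1Ai over 9612 genes with a mean of at least 10 units.

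The series asks what ARID1A does in skin inflammation. ARID1A is a DNA-binding subunit of the SWI/SNF (BAF) chromatin remodelling complex. The gene (ENSG00000117713, GRCh38 chromosome 1, 26693236 to 26782104, plus strand) stood at 136, 141 and 138 units in CTLi replicates 1, 2 and 3, and at 43.9, 46.1 and 46.2 units in ARID1Ai replicates 1, 2 and 3. The mean fell from 138 ± 2.52 to 45.4 ± 1.32 units, to 32.9% of the CTLi level. The log2 change was -1.58 (SE 0.0425, limma adjusted p = 8.8e-18). A two-sided exact permutation test gave p = 0.1, the smallest that 3 against 3 libraries allow.

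**Figure D1:**
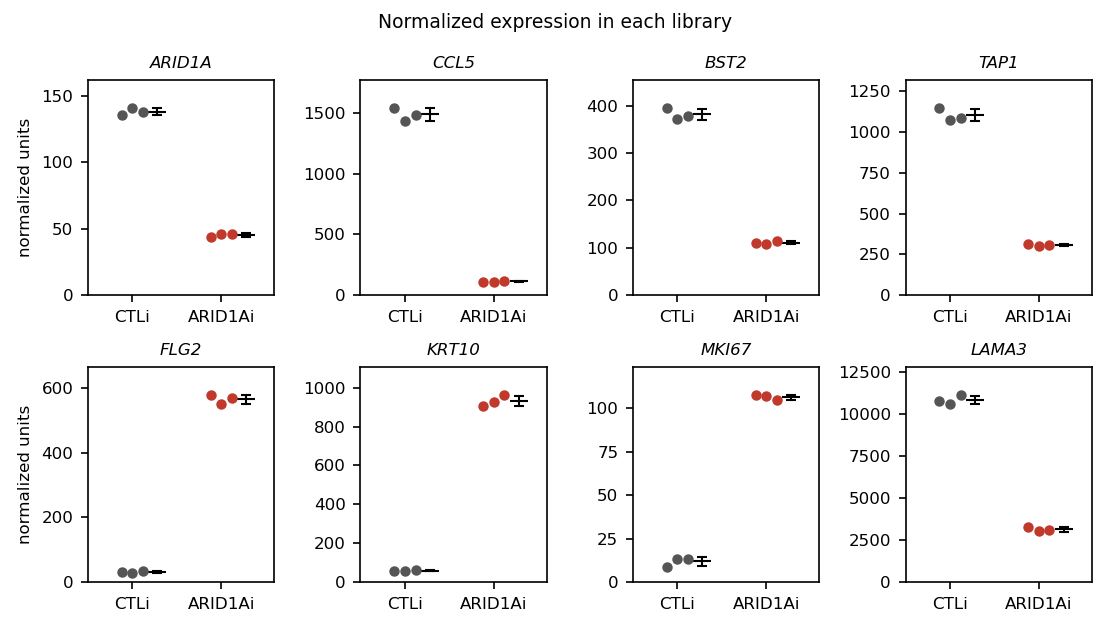
Normalized expression in units (linear vertical axes from 0) of 8 genes in each of the 3 CTLi (grey) and 3 ARID1Ai (red) libraries, with the group mean and SD beside the points. ARID1A lies at 43.9 to 46.2 in the ARID1Ai libraries, and the groups do not overlap for any of the 8 genes.

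With less ARID1A, poly(I:C)-treated keratinocytes had lower levels of interferon-stimulated genes, chemokines and antigen presentation genes, and higher levels of epidermal differentiation, lipid barrier and cell cycle genes. Each of these lists passed camera at a preset correlation, and none did with an estimated correlation (adjusted p = 0.20 for each). The chemokine CCL5, which attracts T cells, fell from 1487 ± 51.8 to 114 ± 5.67 units. The spinous layer keratin KRT10 rose from 60.9 ± 3.41 to 930 ± 27.2 units, and filaggrin (FLG), the precursor of proteins that bundle keratin in the outermost layers, rose from 105 ± 3.69 to 1342 ± 32.5. The proliferation marker MKI67 rose from 12.02 ± 2.61 to 106 ± 1.52 units. Laminin chain LAMA3, part of the anchor between basal cells and the basement membrane, fell from 10820 ± 252 to 3141 ± 127 units.

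Of 14211 genes tested with limma and Benjamini-Hochberg adjustment, 10987 (77.3%) differed between the groups. Of these, 5547 were higher and 5440 lower in ARID1Ai. At a log2 change of at least 1 in either direction, 1371 genes were higher and 1085 lower. The median log2 change over all tested genes was 0.00381.

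**Figure D2:**
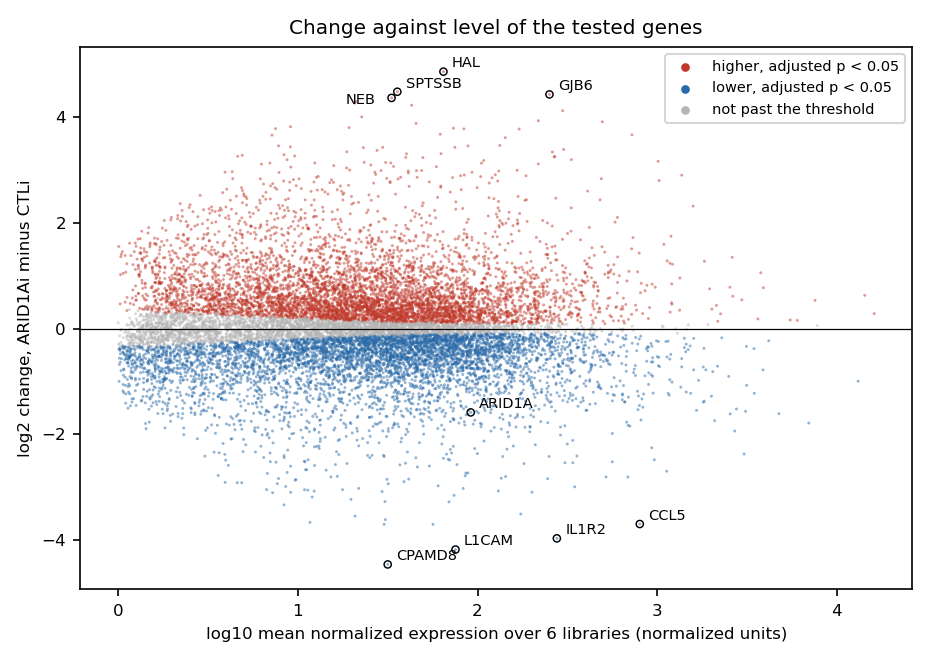
Log2 change (ARID1Ai minus CTLi, pseudocount 1) of each tested gene against the log10 of its mean normalized expression in units over the 6 libraries, coloured by adjusted p below or above 0.05. Labelled genes include ARID1A at -1.58 and CCL5 at -3.69, and genes higher and lower in ARID1Ai are present at all levels.

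The 10 genes with the greatest rise were led by HAL (ENSG00000084110, GRCh38 chromosome 12, 95972662 to 95996365), the enzyme that turns histidine into urocanic acid, which rose from 3.40 ± 0.618 to 126 ± 2.5 units, a log2 change of 4.86 (SE 0.0803, limma adjusted p = 5.2e-21). SPTSSB (chromosome 3, 161344798 to 161372880), a subunit of the enzyme that starts sphingolipid synthesis, changed by 4.48 on the log2 scale. The gap junction gene GJB6 (chromosome 13, 20221962 to 20232365) rose from 21.4 ± 1.63 to 482 ± 8.97 units, a log2 change of 4.43. Loricrin (LORICRIN), a main protein of the cornified envelope, changed by 4.29 and FLG2, a filaggrin relative, by 4.12. The retinol dehydrogenase RDH12 changed by 4.27, the growth factor IGF2 by 4.23, SERPINB13, a protease inhibitor, by 3.93, ANKRD35 by 4.01 and NEB by 4.36. NEB, RDH12 and FLG2 overlap a gene on the opposite strand (RIF1, ZFYVE26 and FLG-AS1), and whether the counting used the strand is not given in the sources used here.

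The 10 greatest falls were led by CPAMD8 (ENSG00000160111, GRCh38 chromosome 19, 16892951 to 17026815), which went from 61.4 ± 2.84 to 1.86 ± 0.405 units, a log2 change of -4.46 (SE 0.0922, limma adjusted p = 1.56e-19). L1CAM (chromosome X, 153861514 to 153886173), a cell adhesion molecule, changed by -4.18. IL1R2 (chromosome 2, 101991960 to 102028544), the decoy receptor for interleukin-1, fell from 520 ± 19.8 to 32.4 ± 1.17 units, a log2 change of -3.97, and the noncoding gene LINC01127 beside it changed by -3.61. The growth factor PDGFB changed by -3.70, the glycosyltransferase gene B3GNT7 by -3.70 and CCL5 (chromosome 17, 35871491 to 35880793) by -3.69. IGFL1 changed by -3.66, GMPR, a guanosine monophosphate reductase, by -3.55 and IGFBP6, which binds insulin-like growth factors, by -3.51.

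Gene lists fixed before the data were examined were tested with limma's camera at a preset correlation of 0.01 between genes. Of 20 lists, 15 passed, 5 as higher and 10 as lower in ARID1Ai. With a correlation estimated from these 6 libraries, 0 of the 20 lists passed, and the adjusted p of the 15 lay between 0.20 and 0.399. The camera calls therefore depend on presetting the correlation, while the counts of members come from the gene tests. Lists with a low estimated correlation lost their call too, among them cholesterol synthesis (0.0484) and double-stranded RNA sensing (0.0847). How much of the loss comes from the size of the correlation, as against estimating it from 6 libraries, was not tested. Counts of members adjusted over the list alone equalled the counts adjusted over all genes tested for every list but that of SWI/SNF subunits. Where every member of a list passed over all genes tested, passing over the list alone was bound to follow and adds no support.

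**Figure D3:**
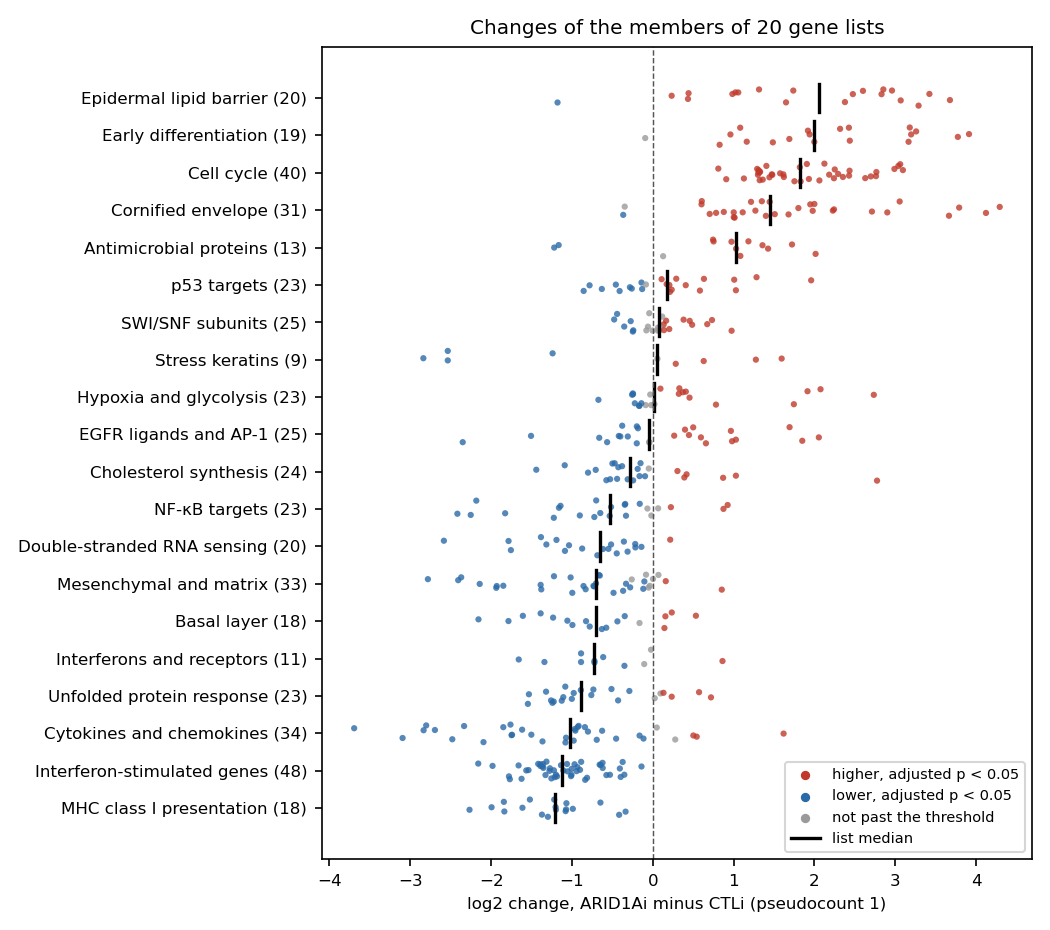
Log2 change (ARID1Ai minus CTLi, pseudocount 1) of each tested member of 20 gene lists, with the number tested in brackets, points coloured by adjusted p below or above 0.05, and the list median as a black bar. The medians run from -1.21 for MHC class I presentation to 2.06 for epidermal lipid barrier genes.

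Interferon-stimulated genes were lower in ARID1Ai throughout: all 48 fell, with a median log2 change of -1.12 (camera adjusted p = 7.56e-19, adjusted p = 0.20 with an estimated correlation). BST2, which tethers budding virus to the cell surface, fell from 382 ± 11.7 to 110 ± 3.10 units, a log2 change of -1.78. SAMD9L changed by -1.98, IFITM1, which hinders viral entry, by -1.77, and IFI35 by -1.66. Of 20 genes that sense double-stranded RNA or pass on the signal, 19 fell and 1 rose (median -0.65, camera adjusted p = 7.11e-07, adjusted p = 0.20 with an estimated correlation). The endosomal sensor TLR3 fell from 76.8 ± 5.35 to 22.04 ± 0.634 units, a log2 change of -1.75, and the cytosolic sensor MDA5 (IFIH1) from 954 ± 80.4 to 364 ± 12.9, a log2 change of -1.38. The transcription factor IRF7 changed by -1.04 and MLKL, the effector of necroptosis, by -1.32.

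Among 11 interferons and their receptor chains, 8 fell, 1 rose and 2 did not pass (median -0.72, camera adjusted p = 0.00872, adjusted p = 0.20 with an estimated correlation). The keratinocyte interferon IFNK fell from 18.9 ± 1.94 to 5.30 ± 0.395 units, and the receptor chain IFNAR2 from 41.8 ± 2.21 to 15.9 ± 0.819. IFNLR1 and IFNGR2 each changed by -0.89. IFNGR1 (-0.02) and IFNL3 (-0.11) did not pass. The member that rose was interferon beta (IFNB1), named after its value was seen, from 0.681 to 2.04 units, a log2 change of 0.86 at a level near the filter.

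Of 34 cytokines and chemokines, 29 fell, 3 rose and 2 did not pass (median -1.03, camera adjusted p = 7.67e-08, adjusted p = 0.20 with an estimated correlation). Beside CCL5, the CXCR3 ligands CXCL10 and CXCL11 fell from 1958 ± 162 to 301 ± 14.1 and from 909 ± 75 to 129 ± 6.51 units, log2 changes of -2.70 and -2.80. TNFSF10 (TRAIL), a death receptor ligand, changed by -1.85. IL6 (0.05) and IL36B (0.28) did not pass. The 3 that rose, named after their values were seen, were the neutrophil chemokine CXCL2 (1.62), IL18 (0.54) and IL24 (0.50). IL24 went from 0.731 ± 0.416 to 1.46 ± 0.658 units, at a level near the filter. Of 23 targets of NF-κB, 17 fell, 3 rose and 3 did not pass (median -0.53, camera adjusted p = 5.74e-05, adjusted p = 0.25 with an estimated correlation). The adhesion molecule ICAM1 fell from 1542 ± 82.7 to 323 ± 15.8 units, TNFAIP2 changed by -2.42, complement factor B (CFB) by -2.18 and the transcription factor IRF1 by -1.83. NFKB1 (0.07) and C3 (-0.02) did not pass. PTGS2 (0.93), PTX3 (0.88) and NFKBIB (0.22) rose and were named after their values were seen. PTX3 went from 0.84 to 2.4 units, also near the filter.

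All 18 genes of MHC class I presentation fell (median -1.21, camera adjusted p = 2.72e-10, adjusted p = 0.20 with an estimated correlation). NLRC5, the transactivator of class I genes, fell from 160 ± 7.96 to 32.6 ± 2.72 units, and the peptide transporter TAP1 from 1103 ± 38.2 to 307 ± 4.30. The immunoproteasome subunit PSMB9 changed by -1.99 and HLA-F by -1.84. Antimicrobial proteins went the other way: 10 of 13 rose, 2 fell and 1 did not pass (median 1.03, camera adjusted p = 0.00165, adjusted p = 0.399 with an estimated correlation). The protease inhibitors SLPI and PI3 rose from 231 ± 24.3 to 935 ± 38.4 and from 341 ± 31 to 1126 ± 61.1 units, the ribonuclease RNASE7 changed by 1.43 and the calprotectin chain S100A8 by 1.08. DEFB103A (0.13) did not pass. Beta-defensin DEFB4A (-1.22) and PGLYRP4 (-1.16) fell and were named after their values were seen.

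Genes of the spinous layer were higher in ARID1Ai, with 18 of 19 risen and 1 not past the threshold (median 2.0, camera adjusted p = 1.48e-10, adjusted p = 0.20 with an estimated correlation). KRT1, the partner of KRT10, rose from 64.8 ± 5.45 to 601 ± 13.9 units, a log2 change of 3.20, beside 3.91 for KRT10. Desmocollin DSC1 changed by 3.78 and dermokine (DMKN) by 3.17. PRDM1 (-0.09) did not pass. Of 31 genes of the granular layer and cornified envelope, 29 rose, 1 fell and 1 did not pass (median 1.45, camera adjusted p = 3.07e-13, adjusted p = 0.20 with an estimated correlation). Involucrin (IVL) rose from 323 ± 29.8 to 2416 ± 123 units, FLG changed by 3.67 and SPRR4 by 3.79. TGM5 (-0.35) did not pass, and SPRR2F fell (-0.37, named after its value was seen). Of 20 genes of the epidermal lipid barrier, 19 rose and 1 fell (median 2.06, camera adjusted p = 7.02e-09, adjusted p = 0.20 with an estimated correlation). The lipoxygenase ALOX12B rose from 8.15 ± 0.631 to 116 ± 3.96 units, ELOVL4, which extends very long fatty acids, changed by 2.85, the protease ASPRV1 by 2.60 and ceramide synthase CERS3 by 2.48. ALOX15B fell (-1.18, named after its value was seen).

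Of 18 basal layer genes, 13 fell, 4 rose and 1 did not pass (median -0.70, camera adjusted p = 0.000243, adjusted p = 0.20 with an estimated correlation). LAMB3, which pairs with LAMA3 in the same laminin, fell from 7166 ± 75.4 to 2353 ± 64.6 units, KRT15 changed by -2.16 and the collagen receptor chain ITGA2 by -1.39. DLK2 (-0.16) did not pass. The 4 that rose, named after their values were seen, were the basal keratins KRT5 (0.53) and KRT14 (0.16), CAV1 (0.24) and DST (0.14). All 40 cell cycle genes rose (median 1.82, camera adjusted p = 4.63e-15, adjusted p = 0.20 with an estimated correlation). The topoisomerase TOP2A rose from 4.56 ± 0.672 to 46.4 ± 3.03 units, a log2 change of 3.10, beside 3.06 for MKI67. CENPF of the kinetochore changed by 3.04 and RRM2, a subunit of ribonucleotide reductase, by 2.99.

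Of 33 mesenchymal, matrix and TGF-beta response genes, 25 fell, 2 rose and 6 did not pass (median -0.70, camera adjusted p = 7.53e-07, adjusted p = 0.20 with an estimated correlation). Fibronectin (FN1) fell from 5105 ± 239 to 987 ± 54.9 units and its receptor chain ITGA5 from 603 ± 12 to 113 ± 2.59. The matrix metalloproteinases MMP10 and MMP9 changed by -2.78 and -1.94. VIM (-0.05) did not pass, and TGFBI (0.85) and TNC (0.16) rose and were named after their values were seen. Of 23 genes of the unfolded protein response, 17 fell, 4 rose and 2 did not pass (median -0.89, camera adjusted p = 5.74e-05, adjusted p = 0.20 with an estimated correlation). The chaperone calreticulin (CALR) fell from 2468 ± 48.4 to 846 ± 27.3 units, HYOU1 changed by -1.32, TRIB3 by -1.24 and PDIA6 by -1.13. XBP1 (0.10) and ASNS (0.02) did not pass. The 4 that rose, named after their values were seen, were EDEM1 (0.57), CHAC1 (0.72), PPP1R15A (0.13) and SESN2 (0.23).

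Of 24 genes of cholesterol synthesis and uptake, 17 fell, 6 rose and 1 did not pass (median -0.28, camera adjusted p = 0.0351, adjusted p = 0.25 with an estimated correlation). This list also missed the threshold after quantile normalization (camera adjusted p = 0.0736) and without limma's trend (camera adjusted p = 0.0584). STARD4 changed by -1.44 and LSS by -1.09, while TM7SF2 rose from 13.03 ± 1.28 to 94.7 ± 2.17 units. SQLE (-0.05) did not pass.

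The other 5 lists did not pass camera, and their members moved in both directions. Of 9 stress keratins, 4 rose, 4 fell and 1 did not pass (median 0.06, mean -0.59, camera direction down, camera adjusted p = 0.485). The simple epithelial keratins KRT19, KRT7, KRT8 and KRT18 fell, by log2 changes of -2.84, -2.54, -2.54 and -1.24. KRT6C (1.595), KRT16 (1.28), KRT17 (0.63) and KRT6A (0.28), keratins of wounded epidermis named after their values were seen, rose, and KRT6B (0.06) did not pass. Of 25 EGF receptor ligands and immediate early factors, 12 rose, 11 fell and 2 did not pass (median -0.04, mean 0.17, camera direction up, camera adjusted p = 0.486). MYC rose from 64.1 ± 2.44 to 269 ± 8.80 units, the ligand EREG changed by 1.85 and FOSB by 1.69, while the feedback inhibitor SPRY2 changed by -1.51. JUNB and JUND (both -0.04) did not pass. Of 23 p53 targets, 13 rose, 9 fell and 1 did not pass (median 0.17, camera adjusted p = 0.541). BTG2 changed by 1.28, AEN by 1.01, MDM2 by 0.63 and XPC by -0.78, and RRM2B (-0.08) did not pass.

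Of 23 genes of hypoxia and glycolysis, 11 rose, 8 fell and 4 did not pass (median 0.02, mean 0.39, camera adjusted p = 0.20). The list passed after quantile normalization (camera adjusted p = 0.0321). Hexokinase HK2 rose from 56.3 ± 0.559 to 241 ± 6.27 units and the glucose transporter SLC2A1 from 175 ± 7.85 to 663 ± 15.5. EGLN3 changed by 2.73 and ANGPTL4 by 1.75. ADM (0.02) and PKM (-0.09) did not pass, while after quantile normalization PKM passed as higher (0.17, limma adjusted p = 0.000506). Of 25 other SWI/SNF subunits, 10 rose, 6 fell and 9 did not pass, and 9 rose and 6 fell when adjusted over the list alone (median 0.08, camera adjusted p = 0.485). The ATPase SMARCA4 rose from 111 ± 3.85 to 185 ± 1.92 units, BCL7A changed by 0.98, SMARCC1 by 0.67 and SMARCD1 by -0.48. ARID1B, the alternative subunit in the place of ARID1A, stood at 82.7 ± 0.465 and 86.3 ± 1.19 units and did not pass (0.06, limma adjusted p = 0.167), nor did SS18 (0.00).

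Few markers of other cell types were among the tested genes. Of 12 fibroblast markers 5 were tested: THY1 (1.01) and FBLN1 (0.59) rose, MMP2 (-0.67) fell, and COL1A1 (0.00) and COL1A2 (0.09) did not pass (camera adjusted p = 0.541). Of 10 melanocyte markers 1 was tested, MITF, which rose by 0.66 to 3.03 ± 0.498 units. Of 15 leukocyte and Langerhans cell markers 3 were tested: CD68 fell from 311 ± 20.9 to 79.7 ± 2.87 units, while the integrin chains ITGAX and ITGAM rose from 0.506 ± 0.164 to 12.04 ± 1.69 and from 0.451 ± 0.154 to 5.96 ± 0.408. Of 9 endothelial markers 3 were tested and all fell (ESAM -0.78, CLDN5 -0.45, EGFL7 -0.27).

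Beside these groups, all 40 cytosolic ribosomal protein genes of the fixed list, which does not hold every such gene, rose (median 0.75, camera adjusted p = 2.66e-15, adjusted p = 0.354 with an estimated correlation). RPL3 rose from 251 ± 12.7 to 735 ± 11.7 units, RPS6 changed by 1.39, RPL4 by 1.36 and RPL5 by 1.30. Of 13 mitochondrial transcripts 7 rose, 1 fell and 5 did not pass (median 0.19, camera adjusted p = 0.129), and the list passed after quantile normalization (camera adjusted p = 0.00114). MT-ATP8 changed by 0.83, MT-ATP6 by 0.58, MT-CO3 by 0.42 and MT-ND3 by 0.36, and MT-ND4 (0.08) did not pass. MT-CO2 was at -0.01 and did not pass, against a rise of 0.26 past the threshold after quantile normalization. MT-CO1, named after its value was seen, fell by 0.23, against a rise of 0.17 past the threshold after quantile normalization. Ribosomal protein, IFITM, HLA, keratin 6, SPRR and beta-defensin genes have close copies, and how reads shared between copies were counted is not given in the sources used here, so the split of reads between such genes is uncertain.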

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

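All alternatives were set before the data were examined, except leaving out the 2 deeper CTLi libraries, which was chosen after seeing the data. ARID1A stayed lower in ARID1Ai under every alternative (-1.51 to -1.60 on the log2 scale). Its limma adjusted p was 1.67e-07 without the trend, against 8.8e-18 with it, so the size of the p-value depends on that setting. The number of genes called was 10987 and lay between 9214 (mean of at least 5 units, 11360 genes tested) and 11056 (no filter), with 10509 to 10680 when 1 library was left out and 9655 without the 2 deeper CTLi libraries. A log2 change of at least 1 left 2456 genes, 1371 higher and 1085 lower, by its construction. Median-ratio rescaling kept 99.6% and quantile normalization 95.1% of the calls. The share of calls that were higher was 50.5%, and 47.5% after quantile normalization, which shifted the median of all genes to -0.04.

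The replicate number as a block gave 11009 calls. Deviations of same-numbered libraries correlated across genes at 0.02, 0.03 and -0.08, so the numbers were not taken as pairs, and the block changed no list call.

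Quantile normalization turned the direction of PKM (0.17), LDHA (0.0771), MT-ND5 (0.0946), MT-CO1 (0.17) and MT-CO2 (0.26), of which LDHA, MT-ND5 and MT-CO1 were named after their values were seen. It took the cholesterol list to an adjusted p of 0.0736, and limma without trend to 0.0584, and it brought the hypoxia list (0.0321) and the mitochondrial list (0.00114) past the threshold. The cause was not tested.

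Camera with an estimated correlation called 0 lists. The adjusted p was 0.2 for 12 lists (interferon-stimulated, sensing, interferons, cytokines, MHC class I, early differentiation, cornified envelope, basal layer, barrier lipids, cell cycle, mesenchymal, unfolded protein), 0.25 for NF-κB targets and cholesterol, 0.399 for antimicrobial and 0.354 for ribosomal proteins. The estimated correlations of the 15 lists called lay between 0.0484 and 0.621. fry, which does not compare a list with other genes, passed stress keratins (4.47e-05), SWI/SNF (0.00042), EGF and AP-1 (0.000709), p53 (0.000246), hypoxia (7.15e-06), fibroblast (0.0154) and mitochondrial (0.015) as well. Over all alternatives, 409 list results kept their direction and side of the threshold, 9 gained and 18 lost a call. For list members and other named genes the counts were 8756 kept, 21 gained, 115 lost and 5 reversed. Count models were not run, since whole reads were not recovered. A simulated log2 change of 0.25 was recovered for 36.0% of changed genes, and how far depth, as against the number of libraries, limits this was not tested. The simulation changed only 200 genes, so its recovery and its share of unchanged genes among the calls need not hold for the data.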

Other observations

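Chosen after the results were seen were the grouping of genes by the start of their symbol, the genes named here, and the tests of other splits on the number of genes, of scaling, of the deeper libraries, of a weaker poly(I:C) response and of gene copies on single chromosomes among neighbouring genes. Of 212 symbol groups with at least 8 tested members, 24 passed camera at the preset correlation, 18 as higher and 6 as lower, and 0 with an estimated correlation (lowest adjusted p = 0.631). All 10 UTP genes and all 8 RRP genes, which process ribosomal RNA precursors, rose (medians 0.90 and 1.08), as did 7 of 8 NOP genes (median 1.20) while 1 fell. The NOL and EXOSC symbol groups, which hold, among others, genes with related functions, did not pass (camera adjusted p = 0.0814 and 0.0917). The nucleolar protein NOP56 rose from 38.6 ± 2.08 to 136 ± 5.74 units and the RNA polymerase I subunit POLR1B from 17.6 ± 0.647 to 50.9 ± 1.07. Of 13 genes of the MMP symbol group, 12 fell (median -1.31), and the collagenase MMP1 fell from 61.7 ± 1.07 to 13.3 ± 1.48 units. Several of this group, among them MMP1, MMP9 and MMP10, are also in the mesenchymal and matrix list, so the group is not separate support. Of 11 annexins 9 fell (median -0.78), among them ANXA6 (-2.15), while ANXA1 (1.24) and ANXA9 (2.44) rose.

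Among other genes named after their values were seen, the cytidine deaminase APOBEC3A went from 1203 ± 164 to 170 ± 5.25 units and APOBEC3G from 43.1 ± 2.22 to 7.17 ± 0.990. The cytosolic phospholipases PLA2G4E and PLA2G4D rose by log2 changes of 2.91 and 2.67, and the noncoding gene H19 rose from 21.3 ± 1.90 to 245 ± 9.18 units, beside its neighbour IGF2 at 4.23.

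The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 10987 genes and the highest other split 0 (limma, with 17 to 38 genes at an unadjusted p under 0.05 in the other splits), so 1 split of 10 gave as many. In the other splits both groups are mixed within each arm, so the group difference widens the spread there. Few or no calls were bound to follow, so the 0 does not show what unrelated libraries would give. For lists, the real split gave 15 and the highest other split 14, so again 1 of 10 gave as many. Each other split still holds 2 libraries of one group against 2 of the other, and camera at the preset correlation then calls 9 to 14 lists, so the number of lists called does not separate the real split from the others well.

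The rise of all 40 ribosomal protein genes of the fixed list (median 0.751) is a pattern that length, GC content or scaling could make. Lists of other genes matched on transcript length and level had a median of -0.182 (upper limit of their central range 0.142), and lists matched on GC content and level a median of -0.166 (upper limit 0.0992). The list median exceeded that of all genes by 0.748, an excess that a factor common to all genes leaves as it is, and by 0.848 after quantile normalization. These values argue against scaling, and against length and GC content of the longest annotated transcript, as the whole source. The expressed transcripts may differ in both, and how closely the lists were matched was not examined. Reads shared with processed pseudogenes stay open and were not tested. The ARID1A knockdown, or another difference between the groups, may be the source, as a hypothesis.

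Cell cycle and differentiation genes rose together while interferon genes fell. Against CTLi replicate 3 alone, the medians of the 4 lists were at least 0.923 of those against the 2 deeper CTLi libraries. This argues against depth for these 4 lists. Over 2456 genes with a log2 change of at least 1 the median ratio was 0.988. Those genes were chosen by the fit to all the CTLi libraries, so their ratio adds little. After a correction for length and GC content, which took up 0.685% of the variance of the changes, each of the 4 medians kept at least 0.917 of its size, which argues against those trends. Of 129 called members of 5 response lists, 93.8% were lower. Since all 6 libraries were stimulated, a weaker poly(I:C) response as a whole cannot be told apart from a direct effect of ARID1A on these genes. A weaker response could come through uptake, sensing or timing. Only a knockdown and a control arm were compared. Any other difference between them, in cultures or in siRNA, cannot be told apart from the level of ARID1A either. The antimicrobial list, left out of that share, had 10 members higher and 2 lower, and a changed cell state after the knockdown is a candidate explanation that was not tested.

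Like changes lay side by side in the genome: in 30 windows of 11 neighbouring tested genes the median change passed the threshold of 1.39 set by 1000 shuffled gene orders, in 5 regions (GRCh38). Not all genes of a region moved alike. On chromosome 1, 19 of 20 rose and 1 fell, and on chromosome 11, 9 of 16 rose and 3 fell. On chromosome 12, 11 of 16 rose and 3 fell, and on chromosome 15, 8 of 14 rose and 6 fell. On chromosome 22, 10 of 14 fell and 2 rose. Around H19 and IGF2 on chromosome 11 (924881 to 2699994), 0 of 16 genes shared a symbol start with another gene of the region, which argues against copies of one family there, although a window still passed in only 59 of 100 draws of 1 gene per symbol start over the whole chromosome. An unnamed gene that overlaps its neighbours IFITM10 and CTSD on the same strand also leaves shared reads open there. In the epidermal differentiation complex on chromosome 1, a window passed in 57 of the draws, where relatives with other names also stayed, and in the keratins on chromosome 12 (52424070 to 53054450), the phospholipases on chromosome 15 (41621134 to 42353666) and the APOBEC3 genes on chromosome 22 (38733290 to 39437060) 0 of these 3 regions kept one. Copies of one family therefore cannot be told apart from a regional change in these 4 regions, since relatives stay in or fewer genes are left, and a shared change of chromatin may be followed up only as a hypothesis.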
